A study of Mus musculus with 20 samples.

How the data were processed

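The tables used were those the authors deposited, with values for 38355 genes in 20 libraries and, per the file headers, log2 fold changes, p-values and adjusted p-values of the authors' own comparisons between genotypes at each day. The submitters name STAR 2.3.0e, DESeq2 1.4.5 and genome build mm10; the roles and order of these tools, the counting tool, the gene annotation and the strand setting are not given in the sources used here. The deposited signal per gene was not raw: per the file headers it is a normalized value, and within each library all nonzero values were whole multiples of 1 step to within 0.1 reads, as for read counts that the authors had divided by a size factor set within each day and rounded to 2 decimals. Whole reads were recovered as the deposited signal divided by that step. They numbered 14.1, 14.9 and 27.0 M in wild type and 31.5 and 28.4 M in labelled knockout at day 0, and 29.9, 20.3 and 3.27 M against 28.7 and 27.5 M at day 4. At day 7 they numbered 26.2, 18.8 and 20.1 M against 22.3 and 26.1 M, and at day 14 26.2, 25.0 and 14.4 M against 23.3 and 19.0 M, in order of replicate number.

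The design was fixed before the data were examined, for raw counts with an edgeR quasi-likelihood test and its own low-count filter. The deposited values were scaled, and limma was used as the main test in its place. Whole reads were recovered, so the scaling did not prevent the planned edgeR test. That test was run on them as an alternative with the filter below. It called fewer genes than limma for the change from day 0 between genotypes. Values were scaled by the trimmed mean of M values (TMM) across all 20 libraries to CPM, and genes with at least 0.5 CPM in at least 2 libraries were kept, which left 15738 genes. The log2 of CPM + 0.5 was fitted in limma 3.58.1 under R 4.3.3 with 1 mean for each of the 8 groups of genotype and day and moderated variances with trend and robust settings. Contrasts compared genotypes at each day, each later day with day 0 within each genotype, and the change from day 0 between genotypes. The p-values were adjusted by Benjamini-Hochberg over all tested genes, and a gene was called at an adjusted p under 0.05. The SE of a difference is the moderated SE of limma; SD is between libraries. The smallest groups have 2 libraries, so calls rest on a variance shared across the 8 groups. The first 3 principal components of the 11064 tested genes with the higher mean levels carried 67.8%, 9.31% and 6.54% of the variance. Labelled knockout replicate 2 lay further from wild type than replicate 1 on the second component at days 4, 7 and 14 (-39.2, -36.4 and -30.6 against -16.9, -12.5 and -11.1). In replicate 2 ribosomal protein genes took 1.07%, 1.10% and 1.37% of the reads and the 50 most abundant genes 20.0%, 18.0% and 18.8%, the highest of the libraries at each of these days.

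Of 25 gene lists fixed before the data were examined, 24 were tested, and the list of sex-linked genes served as a check only: Xist and the Y-linked Ddx3y were present in every library. The tested lists cover regulators of multiciliated cells, centriole amplification, axonemal dynein arms, dynein arm assembly factors, radial spoke, central pair and nexin link genes, intraflagellar transport, the BBSome, markers of basal, secretory, goblet, tuft, neuroendocrine, ionocyte, squamous, fibroblast, smooth muscle and cartilage, leukocyte, and endothelial and glial cells, and the Notch pathway, p53 targets, proliferation, epithelial inflammation, interferon response and immediate early and heat shock genes. Lists were tested with limma camera on the same log2 values with a preset correlation of 0.01, adjusted over the 24 lists within each comparison, and again with a correlation estimated from the data. Of 81 list calls in the 7 comparisons described, 3 held with the estimated correlation. Member counts use the FDR over all genes, and where stated the FDR adjusted over the list alone.

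Named genes follow a rule fixed before the data were examined: Trp73 in every library; all tested regulators of multiciliated cells; in each comparison of genotypes, and in day 14 against day 0, the 10 higher and 10 lower called genes with the largest change whose higher group averaged at least 2 CPM and whose libraries did not overlap between groups, without predicted, clone-named or sex-linked genes; and up to 4 called members of each other list. Coordinates are GRCm38 from GENCODE vM21, in which 36602 of the 38355 deposited gene identifiers and 15579 of the tested genes were found. Symbols are those of the deposited tables, so Dnahc stands for Dnah.

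Whether replicate numbers pair was decided before calls were compared, from the correlation between libraries of each gene's departure from its group mean. Between genotypes at the same day all 8 same-number pairs had a correlation over 0.1 (0.274 to 0.599, median 0.409, 11064 genes), so blocked values stand beside those results where they change a call or move a count by over 1.5 times. With 2 labelled-knockout libraries a day their departures mirror each other, so these pairs are not independent. Of 16 unlike-number pairs 3 also passed 0.1. The highest was 0.511 at day 0, between wild type replicate 3 and labelled knockout replicate 2. Between days, pairs with day 0 passed 0.1 in 3 of 9 cases in wild type and 2 of 6 in labelled knockout, so the comparisons over time, all against day 0, were treated as unpaired. Among days 4, 7 and 14 all 9 wild-type pairs (0.330 to 0.674) and all 6 labelled-knockout pairs (0.648 to 0.803) passed. The main fit treats all 20 libraries as independent, so its p-values do not allow for these correlations. Calls at days 4, 7 and 14 are therefore not independent of each other.

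Alternatives named before the data were examined were scaling by relative log expression or by library size alone, no low-count filter, a filter of 1 CPM in 5 libraries, replicate as a block, only the libraries compared, DESeq2 1.42.0 (on the recovered reads), fry and an estimated correlation for lists, and leaving out each library. The planned main test, edgeR 4.0.16, became an alternative on the recovered reads after the data were seen. Alternatives added after seeing the data were pseudocounts of 0.1 and 2 CPM and the authors' size factors. Leaving out both day 4 libraries titled day 3 was added too (also for the axonemal levels). Leaving out the shallow wild-type library of day 4 was also added and is the same as its leave-one-out run.

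The steps were tested on simulated data, with 5 draws for each of 3 comparisons in which 100 genes were changed 2-fold and 100 changed 4-fold. Of the 2-fold genes 40.6% were called for labelled knockout against wild type at day 14, 42.6% at day 0 and 53.8% for wild type day 14 against day 0; of the 4-fold genes 87.2%, 84.6% and 90.4%, all in the right direction. Unchanged genes made up 7.66%, 13.2% and 12.1% of the calls, above the nominal 5%; the number of draws was raised from 1 to 5 after the first was seen. The authors' own calls were used only for comparison. The authors' deposited table has an adjusted p under 0.05 for 332, 374, 946 and 1146 genes at days 0, 4, 7 and 14, of which 230, 163, 240 and 625 were also called here, all in the same direction. Transcript isoforms, raw reads and motifs were not analysed here.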

Results

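The series held 20 RNA libraries of mouse tracheal epithelial cells grown at an air-liquid interface, a culture in which basal cells give rise to multiciliated and secretory cells. Cells came from wild-type mice and from mice labelled knockout for p73, and were harvested on days 0, 4, 7 and 14. Each day had 3 wild-type and 2 labelled-knockout libraries; the series text speaks of 3 replicates of each genotype. The reads recovered per library ranged from 3.27 M (wild type day 4, replicate 3) to 31.5 M (labelled knockout day 0, replicate 1). The titles of both day 4 libraries of replicate 1 name day 3, and they were kept at day 4 as their other labels state. Of 38355 genes, 15738 were tested with limma, and a gene was called at an adjusted p (FDR) under 0.05. Levels below are means of scaled CPM ± SD, with n = 3 for wild type and n = 2 for labelled knockout. Changes are log2 differences ± SE on a log2(CPM + 0.5) scale, which understates the fold changes of genes with low levels.

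Trp73, the gene encoding p73 (ENSMUSG00000029026, chromosome 4, 154056253 to 154140208 in GRCm38), was not called lower in the libraries labelled knockout at any day. At day 0 those libraries held 49.1 and 48.7 CPM of Trp73, against 2.70, 2.21 and 1.07 CPM in wild type. The day 0 difference was 4.37 ± 0.36 (FDR 8.47e-06), and it kept its call with each library left out. At day 4 the labelled-knockout libraries held 35.0 and 27.4 CPM and wild type 9.80, 21.99 and 23.3 CPM (difference 0.83 ± 0.36, FDR 0.515). At day 7 the levels were 30.2 and 21.2 CPM against 22.1, 27.0 and 34.9 CPM (-0.12 ± 0.36, FDR 1). At day 14 they were 30.5 and 16.7 CPM against 23.3, 27.0 and 27.3 CPM (-0.19 ± 0.36, FDR 0.961). For Trp73 the authors' deposited table gives log2 fold changes of 4.3, 0.73, -0.1 and -0.09 at the 4 days. Values per gene cannot check the deletion, because the labels do not say which part of the gene was removed, and reads by exon were not analysed here. Directions below therefore compare libraries by their label.

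**Figure D1:**
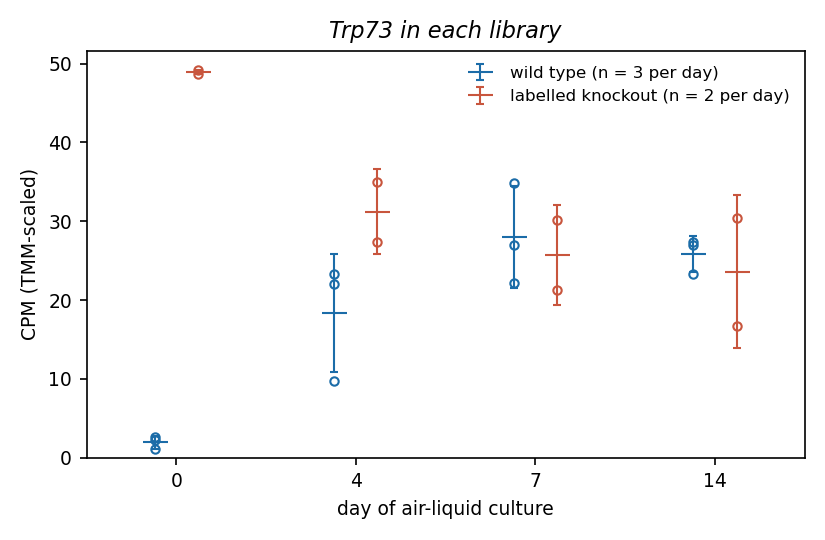
Trp73 in each of the 20 libraries by day, with group mean and SD (n = 3 wild type, n = 2 labelled knockout per day).

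What changed as wild-type cultures differentiated? Between day 0 and day 14 the wild-type cultures gained the transcripts of motile cilia and of the regulators of multiciliated cells, while most basal, squamous and immediate early genes on the lists fell. Sec14l3 (ENSMUSG00000054986, chromosome 11, 4064841 to 4077736) rose from 3.87 ± 1.64 to 2911 ± 108 CPM (9.46 ± 0.42, FDR 1.60e-10). Dnahc6, a heavy chain of the inner dynein arm (ENSMUSG00000052861, chromosome 6, 73017606 to 73221651), rose from 0.22 ± 0.06 to 187 ± 35.4 CPM (8.01 ± 0.35, FDR 1.58e-10). Trp73 rose by 3.46 ± 0.32 (FDR 2.34e-07). Ndufa4l2, a mitochondrial protein induced by hypoxia (ENSMUSG00000040280, chromosome 10, 127514967 to 127517154), fell from 186 ± 12.2 to 0.10 ± 0.05 CPM (-8.28 ± 0.30, FDR 2.61e-11). The hypoxia-induced carbonic anhydrase Car9 fell by 5.54 ± 0.30 (FDR 9.74e-10).

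Of the 12 tested regulators of multiciliated cells, 9 rose in wild type by day 14. They included Mcidas (5.28 ± 0.28, FDR 7.24e-10), Ccno (1.76 ± 0.53 to 90.4 ± 1.25 CPM, 5.36 ± 0.28, FDR 5.93e-10) and Foxj1 (18.8 ± 5.47 to 485 ± 7.14 CPM, 4.70 ± 0.28, FDR 1.98e-09). Rfx2, a transcription factor of ciliary genes, rose by 1.97 ± 0.24 (FDR 4.73e-06), and Gmnc and Myb rose by 5.10 ± 0.30 (FDR 1.66e-09) and 5.69 ± 0.38 (FDR 4.34e-09). E2f4, E2f5 and Tfdp1 did not pass the test. All 24 axonemal dynein arm genes, all 28 radial spoke, central pair and nexin link genes, all 12 dynein arm assembly factors and all 17 centriole amplification genes rose, with 26 of 27 intraflagellar transport genes and 8 of 9 BBSome genes. The median changes were 6.16 for dynein arms (camera adjusted p 1.09e-24) and 5.51 for radial spokes (1.09e-24). For assembly factors they were 3.65 (4.86e-12), for centriole amplification 1.98 (5.46e-11), for intraflagellar transport 1.85 (5.82e-16), for the BBSome 1.77 (2.08e-06) and for regulators 4.78 (1.34e-08). These list calls were lost with a correlation estimated from the data, with adjusted p = 0.0858 for centriole amplification and adjusted p = 0.0782 with an estimated correlation for the others. Examples were the dynein heavy chain Dnahc5 (1.73 ± 0.78 to 449.9 ± 77.4 CPM), the deuterosome gene Ccdc67 (7.09 ± 0.34, FDR 2.74e-10), the assembly factor Zmynd10 (6.28 ± 0.34, FDR 7.59e-10) and Ift57 (2.58 ± 0.17, FDR 5.36e-09).

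Basal markers moved the other way: 13 of 17 fell and 2 rose (camera adjusted p 3.45e-05; adjusted p = 0.0782 with an estimated correlation), among them Krt17 (430.4 ± 27.3 to 43.6 ± 17.3 CPM, -3.37 ± 0.39, FDR 2.71e-06). Of 16 squamous and cornified markers 11 fell (0.00184; adjusted p = 0.275 with an estimated correlation), such as Sprr1a (-3.08 ± 0.47, FDR 5.47e-05). Of 17 epithelial inflammation genes 6 fell (median -1.01, 0.018; adjusted p = 0.473 with an estimated correlation), with Cxcl1 at -2.44 ± 0.48 (FDR 0.000605). Of 14 immediate early and heat shock genes 9 fell and 1 rose (0.00137; adjusted p = 0.0852 with an estimated correlation), with Atf3, a stress-induced transcription factor, at -4.96 ± 0.45 (FDR 1.71e-07). Secretory markers moved in both directions, with 4 of 15 up and 2 down (camera adjusted p 0.378). Cyp2f2, a cytochrome of club cells, rose by 2.59 ± 0.21 (FDR 4.15e-08), while the mucin Muc5b fell by 1.96 ± 0.26 (FDR 1.02e-05). Of 12 goblet markers 5 fell and 1 rose (0.107), and Muc5ac fell from 29.8 ± 5.89 to 5.25 ± 0.14 CPM (FDR 4.49e-07). Of 25 proliferation genes 4 fell and 1 rose (0.0739), and none passed when adjusted over the list alone; Mki67 fell by 1.71 ± 0.54 (FDR 0.0186), a call lost without wild type day 0 replicate 1 or 2 or wild type day 14 replicate 1 or 2 (highest FDR 0.0880, without wild type day 0 replicate 2).

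Markers of cells other than epithelium also moved with time in wild type. Of 11 fibroblast markers 7 fell and 1 rose (camera adjusted p 0.0109; adjusted p = 0.420 with an estimated correlation). Of 6 smooth muscle and cartilage markers 3 fell and 1 rose (0.0425; adjusted p = 0.236 with an estimated correlation), with Acta2 at -3.20 ± 0.36 (FDR 2.00e-06); that list call was lost without wild type day 0 replicate 2 (0.0555) or wild type day 14 replicate 1 (0.0736). Leukocyte markers (3 of 6 down, 1 up, 0.186) and endothelial and glial markers (1 of 4 up, 1 down, 0.703) were not called as lists. The 1 leukocyte marker that rose was the lysozyme Lyz2 (4.44 ± 0.76, FDR 0.000159). Other leukocyte genes on that list, Ptprc, Cd52, Tyrobp, Fcer1g, Emr1, Cd3e and Cd79a, did not pass the low-count filter and were not tested.

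In wild type 4250 genes were called at day 4 against day 0 (2138 higher, 2112 lower), 5599 at day 7 (2987 higher, 2612 lower) and 6359 at day 14 (3421 higher, 2938 lower). By day 4 the list of regulators already had 9 of 12 members up (median 4.12, camera adjusted p 7.36e-11), and dynein arm genes had 23 of 24 up (4.29, 1.54e-26), both with adjusted p = 0.0933 with an estimated correlation. The dynein arm median reached 5.68 at day 7 (3.84e-26; adjusted p = 0.0634 with an estimated correlation). Directions depended in part on scaling: by library size alone the higher share of calls was 62.5% at day 4 against 50.3% with the scaling used, 64.7% against 53.3% at day 7, and 62.1% against 53.8% at day 14. Of 114 called genes named by the rule at day 14, 107 kept their call with each library left out.

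How did the libraries labelled knockout differ at day 0, before differentiation at the air interface? They held more transcripts of squamous, cornified epithelium and of inflammatory signals, and fewer of secretory products. Tgm3, a transglutaminase that crosslinks the cornified envelope (ENSMUSG00000027401, chromosome 2, 130012349 to 130050399), stood at 54.9 ± 60.3 CPM against 0.19 ± 0.11 CPM in wild type (5.70 ± 0.60, FDR 6.90e-05). Krt13, a keratin of stratified mucosa (ENSMUSG00000044041, chromosome 11, 100117327 to 100121566), stood at 2458 ± 980.0 against 82.3 ± 64.2 CPM (5.34 ± 0.96, FDR 0.00508). Muc5b, a major airway mucin (ENSMUSG00000066108, chromosome 7, 141839070 to 141873084), was lower at 79.7 ± 7.60 against 663 ± 43.0 CPM (-3.05 ± 0.29, FDR 3.06e-05). The secreted airway protein Bpifb1 (ENSMUSG00000027485, chromosome 2, 154190818 to 154220369) stood at 4.54 ± 0.68 against 32.4 ± 11.4 CPM (-2.66 ± 0.35, FDR 0.0004).

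By list, 10 of 16 squamous and cornified markers were higher at day 0 and none was lower, with 13 higher when adjusted over the list alone (median 1.88, camera adjusted p 1.13e-15; adjusted p = 0.0174 with an estimated correlation). Examples were Krt6b (126 ± 39.6 against 4.90 ± 2.19 CPM, FDR 0.0006) and Krt4 (1.46 ± 0.27, FDR 0.00686). Sprr2f, which is not on that list and was named for its large change, was also higher (6.06 ± 0.97, FDR 0.00208). Secretory markers went down: 4 of 15, and 11 when adjusted over the list alone (median -1.10, 1.17e-14; adjusted p = 0.0131 with an estimated correlation), including Muc5b, Bpifb1 and Scgb3a2 (107 ± 43.8 against 370.0 ± 112 CPM, -1.79 ± 0.32, FDR 0.00453). Of 17 epithelial inflammation genes 5 were higher, and 10 when adjusted over the list alone (median 2.10, 1.69e-12; adjusted p = 0.0977 with an estimated correlation). They included the cytokine Il1a (91.3 ± 59.7 against 1.70 ± 2.00 CPM, 5.59 ± 0.65, FDR 0.000145), the neutrophil attractant Cxcl2 (3.83 ± 0.39, FDR 6.90e-05) and Tslp (2.28 ± 0.31, FDR 0.000597). Of 12 goblet markers 2 were lower, with 4 lower and 1 higher over the list alone (camera adjusted p 0.0107; adjusted p = 0.493 with an estimated correlation), among them Muc5ac (-1.68 ± 0.26, FDR 0.0018) and Fcgbp (-2.25 ± 0.43, FDR 0.00765). The goblet list, with a median of -0.48, lost its call without wild type day 0 replicate 1 (median 0.03, 0.222) or labelled knockout day 0 replicate 2 (-0.17). Its median was -0.82 without labelled knockout day 0 replicate 1 and -0.81 without wild type day 0 replicate 3.

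Basal markers had 2 of 17 higher and 3 over the list alone (median 0.25, camera adjusted p 0.0578). Krt14, a keratin of basal cells, was higher at 1848 ± 988 against 287 ± 182 CPM (2.79 ± 0.48, FDR 0.00396). None of 25 proliferation genes was called with limma, although 18 passed an unadjusted p under 0.05 and 14 were higher when adjusted over the list alone; edgeR called 0 and DESeq2 called 3. That list was shifted up with a median of 1.42 (8.89e-12; adjusted p = 0.493 with an estimated correlation). The median rested largely on 1 library: it was 0.57 (0.0428) without labelled knockout day 0 replicate 1, 2.20 without replicate 2 and 0.91 without wild type day 0 replicate 3. Of 12 regulators of multiciliated cells limma and edgeR called 0 at day 0, DESeq2 called 1, and 1 passed an unadjusted p under 0.05 (camera adjusted p 0.389); Gmnc stood at -1.04 ± 0.33 (FDR 0.144). No member was called by limma or edgeR in the lists for intraflagellar transport (median -0.19, camera adjusted p 0.00246; adjusted p = 0.620 with an estimated correlation), radial spokes (-0.24, 0.0111; adjusted p = 0.737 with an estimated correlation), dynein arms (-0.12, 0.0277; adjusted p = 0.737 with an estimated correlation) and the BBSome (-0.17, 0.0212; adjusted p = 0.493 with an estimated correlation). At an unadjusted p under 0.05 these lists had 5, 1, 3 and 2 lower members, and DESeq2 called 1, a dynein arm gene. All 4 lost the list call without wild type day 0 replicate 1 (0.121, 0.147, 0.134 and 0.222). Dynein arms and radial spokes lost it without labelled knockout day 0 replicate 1 (0.0598 and 0.0777), and intraflagellar transport, the BBSome and dynein arms without replicate 2 (0.422, 0.422 and 0.146). In that run the BBSome median turned to 0.07 and that of intraflagellar transport was -0.003. Without labelled knockout day 0 replicate 1 these medians were -0.41 and -0.34. With replicate as a block the calls of dynein arms (0.213), radial spokes (0.119) and the BBSome (0.0714) were lost.

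In all, 350 genes were called at day 0, 285 higher and 65 lower. Leaving out wild type day 0 replicate 3 gave 194, DESeq2 on recovered reads gave 577, and a fit with the 5 day 0 libraries alone gave 2, with 1091 at an unadjusted p under 0.05. Of 34 called genes named by the rule, 19 kept their call with each library left out, among them Trp73, Tgm3, Krt13, Il1a, Muc5b, Bpifb1, Muc5ac and Cxcl2. The other 15 lost it without at least 1 library; among them were Krt14 (FDR 0.0827), Scgb3a2 (0.0944) and Fcgbp (0.168) without labelled knockout day 0 replicate 1, and Krt4 (0.0841) without replicate 2.

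**Figure D2:**
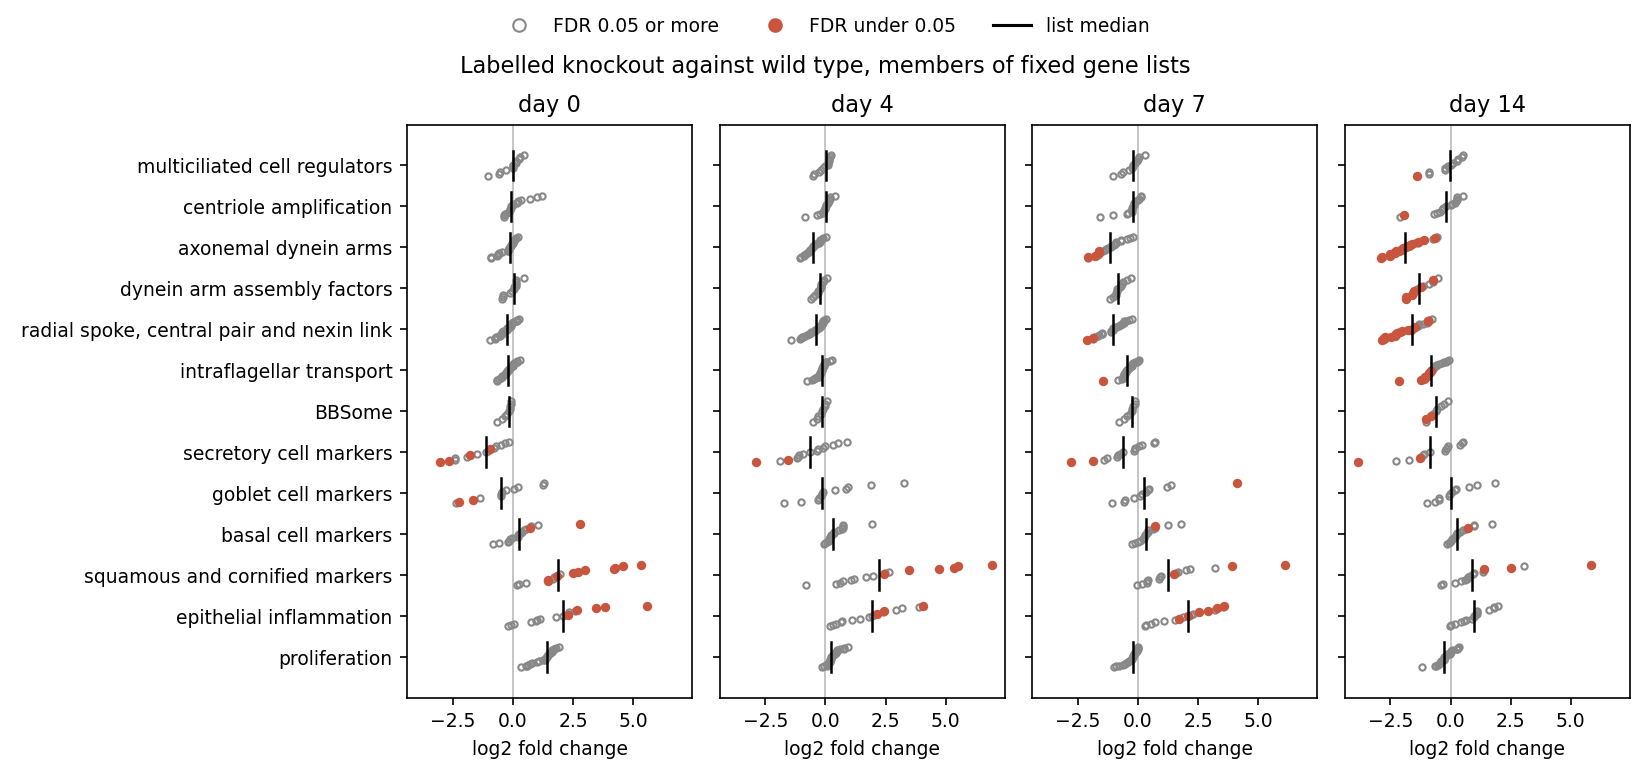
Members of 13 fixed gene lists, labelled knockout against wild type at each day (n = 2 against n = 3); filled points had an FDR under 0.05 and black lines mark list medians.

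What differed at day 4? The squamous program stayed higher in the libraries labelled knockout, the secretory products Bpifb1 and Muc5b stayed lower, and Sntn of motile cilia was lower. Tgm3 stood at 158 ± 85.4 against 0.31 ± 0.12 CPM (7.51 ± 0.60, FDR 5.52e-06), and Krt13 at 2807 ± 821 against 31.0 ± 29.8 CPM (6.91 ± 0.96, FDR 0.00109). Sntn, which encodes the cilium tip protein sentan (ENSMUSG00000044772, chromosome 14, 13670876 to 13683148), was lower at 0.33 ± 0.08 against 16.5 ± 12.7 CPM (-3.78 ± 0.77, FDR 0.0171). Cnn1, a smooth muscle calponin (ENSMUSG00000001349, chromosome 9, 22099216 to 22109630), stood at 0.50 ± 0.28 against 8.82 ± 2.09 CPM (-3.22 ± 0.48, FDR 0.00194).

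Of 16 squamous markers 6 were higher at day 4, and 12 over the list alone (median 2.21, camera adjusted p 1.63e-20; adjusted p = 0.0122 with an estimated correlation), such as Cnfn (5.52 ± 0.72, FDR 0.000687) and Krt4 (2734 ± 194 against 506 ± 89.4 CPM, 2.45 ± 0.27, FDR 0.000213). Of 17 inflammation genes 3 were higher, and 12 over the list alone (1.94, 6.04e-14; adjusted p = 0.0732 with an estimated correlation), including Il1a (4.07 ± 0.65, FDR 0.00336) and Tnf (2.16 ± 0.46, FDR 0.0243). Secretory markers had 2 of 15 lower, with 5 lower and 1 higher over the list alone (-0.65, 0.000119; adjusted p = 0.135 with an estimated correlation): Bpifb1 (-2.90 ± 0.35, FDR 0.000354) and Muc5b (249 ± 142 against 677 ± 55.8 CPM, -1.57 ± 0.29, FDR 0.00819). That list lost its call without labelled knockout day 4 replicate 1 (median -0.28, 0.210). The inflammation median was 0.74 without labelled knockout day 4 replicate 2. Of 6 smooth muscle and cartilage markers Cnn1 and Myh11 (-2.02 ± 0.35, FDR 0.00604) were lower (camera adjusted p 0.000287; adjusted p = 0.0732 with an estimated correlation). Of 6 leukocyte markers the integrin Itgam was higher at 31.7 ± 18.95 against 1.45 ± 0.63 CPM (3.96 ± 0.52, FDR 0.000712), and the list itself was not called (0.197).

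No axonemal or regulator gene on the lists was called at day 4 by limma, edgeR or DESeq2, and 0 of the 12 regulators passed an unadjusted p under 0.05. The dynein arm list was shifted down (median -0.54, camera adjusted p 2.89e-06; adjusted p = 0.630 with an estimated correlation; 2 of 24 members at an unadjusted p under 0.05), as were the lists for radial spokes (-0.39, 3.12e-05; adjusted p = 0.676 with an estimated correlation; 3 of 28) and for intraflagellar transport (-0.16, 0.0027; adjusted p = 0.676 with an estimated correlation; 3 of 27). Assembly factors were shifted with a median of -0.21 (0.0466; adjusted p = 0.759 with an estimated correlation; 0 of 12 at an unadjusted p under 0.05). Foxj1 stood at -0.02 ± 0.31 (FDR 0.997). Without wild type day 4 replicate 2 or replicate 3 the calls were lost for radial spokes (0.0761 and 0.0981), intraflagellar transport (0.187 and 0.226) and assembly factors (0.568 and 0.693). Without labelled knockout day 4 replicate 2 they were lost for intraflagellar transport (0.0739) and assembly factors (0.340), and with replicate as a block for assembly factors (0.218). The dynein arm median ranged from -0.25 without labelled knockout day 4 replicate 2 to -1.08 without wild type day 4 replicate 1. The radial spoke median ranged from -0.09 without wild type day 4 replicate 3 to -0.93 without wild type day 4 replicate 1. Without these libraries that of intraflagellar transport was -0.04 and -0.36, and that of assembly factors -0.08 and -0.60. Basal markers had 0 of 17 called by limma and edgeR, 2 by DESeq2 and 5 at an unadjusted p under 0.05 (median 0.30, 0.000287, or adjusted p = 0.135 with an estimated correlation). That median was 0.49 without wild type day 4 replicate 2. Immediate early and heat shock genes had 0 of 14 called by the 3 tools and 1 at an unadjusted p under 0.05 (median 0.47, camera adjusted p 0.00251; adjusted p = 0.135 with an estimated correlation); that list call was lost without labelled knockout day 4 replicate 1 (0.339).

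In all, 180 genes were called at day 4, 143 higher and 37 lower, and 91 of the higher genes were also higher at day 0 against 2.59 for independent lists. Both lists use the same variance estimate for each gene, so they are not independent and some excess was built in. Replicate numbers paired across genotypes at the same day, and with replicate as a block the count was 291. It was 311 without wild type day 4 replicate 1, 94 without wild type day 4 replicate 3, 44 without labelled knockout day 4 replicate 2 and 285 without both libraries titled day 3. DESeq2 gave 362, and the 5 day 4 libraries alone gave 50, with 1165 at an unadjusted p under 0.05. Of 27 called genes named by the rule 11 kept their call with each library left out, among them Tgm3, Krt13, Cnfn, Krt4, Cnn1, Bpifb1 and Itgam; the other 16 lost it without at least 1 library. Sntn lost it in 4 of the 5 runs, without labelled knockout day 4 replicate 2 (FDR 0.191) or 1 (0.114) and without wild type day 4 replicate 3 (0.110) or 2 (0.0723). Without labelled knockout day 4 replicate 2 so did Myh11 (0.164), Il1a (0.129) and Tnf (0.584), without wild type day 4 replicate 3 Tnf (0.140), and without labelled knockout day 4 replicate 1 Muc5b (0.150).

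What differed at day 7? Genes of the axoneme were now called lower in the libraries labelled knockout, beside the squamous and inflammatory genes that stayed higher. Sntn stood at 1.72 ± 1.48 against 45.6 ± 14.4 CPM (-4.51 ± 0.77, FDR 0.00571), and Cdhr1, a cadherin family member, at 0.45 ± 0.21 against 13.1 ± 6.73 CPM (-3.75 ± 0.53, FDR 0.00178). Dnahc6 stood at 34.5 ± 3.82 against 123 ± 39.8 CPM (-1.77 ± 0.39, FDR 0.0283). Tgm3 was still higher at 92.0 ± 40.0 against 0.14 ± 0.06 CPM (7.11 ± 0.60, FDR 1.96e-05).

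Of 24 dynein arm genes 5 were lower at day 7 (2 with edgeR, 10 with DESeq2), and 20 over the list alone (median -1.18, camera adjusted p 1.71e-20; adjusted p = 0.104 with an estimated correlation), including Dnahc10 (-1.64 ± 0.35, FDR 0.0248) and Dnahc3 (12.1 ± 2.16 against 54.6 ± 16.5 CPM, -2.08 ± 0.47, FDR 0.0359). Of 28 radial spoke genes 2 were lower (0 with edgeR, 10 with DESeq2), and 14 over the list alone (-1.04, 4.62e-18; adjusted p = 0.168 with an estimated correlation): the central pair gene Hydin (-2.14 ± 0.51, FDR 0.045) and Tcte1 (-1.86 ± 0.44, FDR 0.046). Of 27 intraflagellar transport genes Traf3ip1 was lower (47.9 ± 3.19 against 132 ± 23.1 CPM, -1.44 ± 0.27, FDR 0.0103), and 5 over the list alone (-0.48, 7.61e-10; adjusted p = 0.168 with an estimated correlation). Assembly factors had 0 of 12 called by the 3 tools and 9 at an unadjusted p under 0.05 (-0.82, 7.37e-08; adjusted p = 0.168 with an estimated correlation). The BBSome had 0 of 9 called by any tool and 2 at an unadjusted p under 0.05 (median -0.26, 0.00452; adjusted p = 0.257 with an estimated correlation), and centriole amplification 0 of 17 with 2 at that p (-0.22, 0.0367; adjusted p = 0.507 with an estimated correlation). Of 12 regulators limma and edgeR called 0, DESeq2 called 1 and 2 passed an unadjusted p under 0.05 (camera adjusted p 0.0507); Rfx2 stood at -1.06 ± 0.27 (FDR 0.0608) and Foxj1 at -0.63 ± 0.31 (FDR 0.572).

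Of 17 inflammation genes 6 were higher at day 7, and 12 over the list alone (median 2.09, camera adjusted p 1.05e-17; adjusted p = 0.0519 with an estimated correlation), such as Cxcl1 (12.9 ± 8.75 against 1.08 ± 0.20 CPM, 2.91 ± 0.54, FDR 0.00946). Squamous markers had 3 of 16 higher, and 7 over the list alone (1.24, 4.61e-12; adjusted p = 0.0519 with an estimated correlation), with Krt13 at 6.12 ± 0.96 (FDR 0.00309) and Krt6b at 3.89 ± 0.63 (FDR 0.00392). Secretory markers had 2 of 15 lower (-0.63, 0.0028; adjusted p = 0.207 with an estimated correlation): Muc5b (123 ± 5.499 against 448 ± 46.9 CPM, -1.85 ± 0.29, FDR 0.00298) and Bpifb1 (-2.77 ± 0.35, FDR 0.00114). Basal markers had 1 of 17 higher, Pdpn (0.71 ± 0.17, FDR 0.0413; list 0.000107; adjusted p = 0.104 with an estimated correlation). Leukocyte markers had 1 of 6 higher, Itgam at 3.603 ± 0.522 (FDR 0.00224; list 0.000804; adjusted p = 0.0918 with an estimated correlation). Fibroblast markers had 0 of 11 called by limma and edgeR, 3 by DESeq2 and 4 at an unadjusted p under 0.05 (median 1.92, 6.35e-06; adjusted p = 0.168 with an estimated correlation). Interferon genes had 0 of 20 called by limma and edgeR, 1 by DESeq2 and 5 at an unadjusted p under 0.05 (0.41, 3.03e-05; adjusted p = 0.265 with an estimated correlation). The goblet marker Itln1, an intelectin, was higher (4.13 ± 0.96, FDR 0.0391), as was the smooth muscle actin Acta2 (2.16 ± 0.40, FDR 0.0103). The list calls of the BBSome (0.119), basal markers (median 0.15 in place of 0.32, 0.146), fibroblast markers (0.54 in place of 1.92, 0.146), secretory markers (-0.38, 0.119) and centriole amplification (0.270) were lost without labelled knockout day 7 replicate 1, the last also without wild type day 7 replicate 3 (0.181) and with replicate as a block (0.185).

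In all, 246 genes were called at day 7, 125 higher and 121 lower. The count was 138 without wild type day 7 replicate 1, 70 without wild type day 7 replicate 3, 88 without labelled knockout day 7 replicate 1, 36 without labelled knockout day 7 replicate 2, 524 with DESeq2 and 402 with the 5 day 7 libraries alone. Of 38 called genes named by the rule 7 kept their call with each library left out: Tgm3, Gpr115, Cdhr1, Fam166b, Diras2, Bpifb1 and Muc5b. Without labelled knockout replicate 1 the FDR was 0.103 for Sntn and at its highest for Dnahc10 (0.179), Hydin (0.307) and Tcte1 (0.305). Leaving out labelled knockout replicate 2 ended the calls of Krt13 (0.0707), Krt6b (0.126) and Itgam (0.0676), and gave the highest FDR for Dnahc6 (0.237), Dnahc3 (0.284), Traf3ip1 (0.141), Cxcl1 (0.209), Acta2 (0.134), Itln1 (0.441) and Pdpn (0.413). These genes other than Sntn, Krt13, Krt6b and Itgam also lost the call without wild type day 7 replicate 3, and Itln1, Pdpn, Hydin and Tcte1 without any 1 of the 5 libraries. With replicate as a block Dnahc3 (FDR 0.0589), Hydin (0.0526), Tcte1 (0.0561) and Olfm4 (0.0782) missed the threshold, and the neuroendocrine and tuft lists were called (adjusted p 0.0459 each).

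What differed at day 14? The libraries labelled knockout held less of most axonemal transcripts on the lists, while 1 of the 12 regulators upstream of that program was called lower. Sntn stood at 2.41 ± 2.35 against 106 ± 32.1 CPM (-5.43 ± 0.77, FDR 0.000614), and Cdhr4, a cadherin family member (ENSMUSG00000032595, chromosome 9, 107992497 to 107999684), at 1.405 ± 0.344 against 61.0 ± 9.12 CPM (-5.01 ± 0.51, FDR 4.62e-05). Dnahc6 stood at 31.6 ± 3.34 against 187 ± 35.4 CPM (-2.53 ± 0.39, FDR 0.00123). Krt13 was still higher at 539.8 ± 93.5 against 10.9 ± 9.30 CPM (5.85 ± 0.96, FDR 0.00192), as was Cybb, a subunit of the phagocyte oxidase, at 214 ± 40.4 against 33.7 ± 10.4 CPM (2.68 ± 0.45, FDR 0.00217).

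Of 12 regulators limma called only Rfx2 lower (ENSMUSG00000024206, chromosome 17, 56775897 to 56831013; 19.7 ± 7.53 against 51.5 ± 8.68 CPM, -1.402 ± 0.268, FDR 0.00573), and 2 were lower over the list alone (list median -0.03, camera adjusted p 0.505). edgeR called 1 of them lower, DESeq2 called 2, and 3 passed an unadjusted p under 0.05. Foxj1, a transcription factor of motile cilia (ENSMUSG00000034227, chromosome 11, 116330704 to 116335399), stood at 271 ± 88.5 against 485 ± 7.14 CPM without passing the test (-0.88 ± 0.31, FDR 0.173), and Rfx3 stood at -0.88 ± 0.28 (FDR 0.1). Gmnc (0.03 ± 0.33, FDR 0.996), Mcidas (0.46 ± 0.31, FDR 0.695), Ccno (113 ± 30.5 against 90.4 ± 1.25 CPM, FDR 0.879) and Myb (121 ± 17.99 against 144 ± 21.3 CPM, FDR 0.952) did not differ by the test; a p that misses the threshold does not show equal levels. Centriole amplification genes had 1 of 17 lower, Ccdc78 (-1.94 ± 0.46, FDR 0.0215), and 2 over the list alone (list median -0.19, camera adjusted p 0.259).

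**Figure D3:**
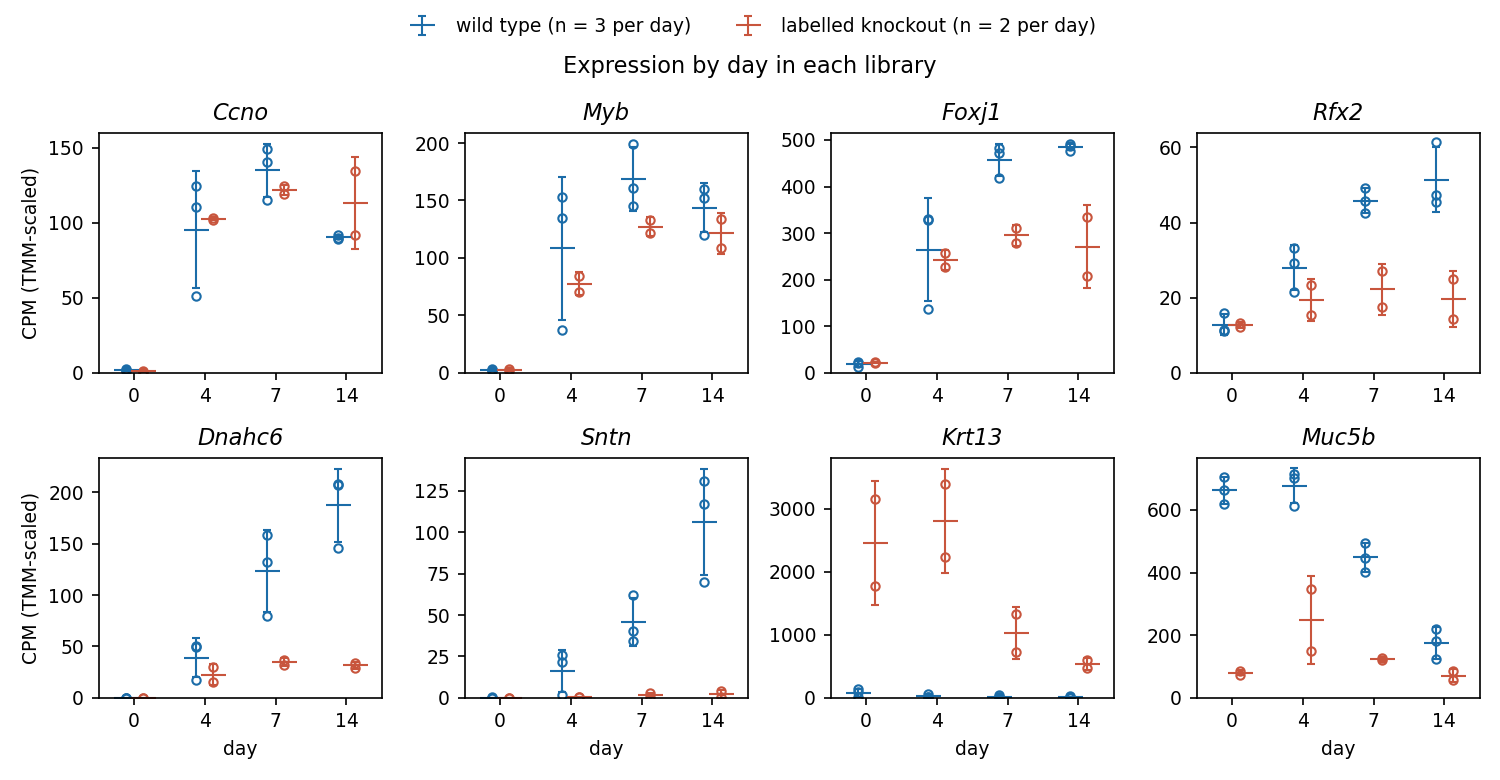
Levels by day of 4 regulators, 2 genes of motile cilia, Krt13 and Muc5b in each library, with group mean and SD (n = 3 wild type, n = 2 labelled knockout per day).

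Of 24 dynein arm genes 19 were lower at day 14, and 23 over the list alone (median -1.91, camera adjusted p 7.70e-29; adjusted p = 0.115 with an estimated correlation), including Dnahc3 (11.4 ± 2.12 against 89.8 ± 20.6 CPM, -2.90 ± 0.47, FDR 0.00192) and Dnahc10 (-2.07 ± 0.35, FDR 0.00228). Of 28 radial spoke, central pair and nexin link genes 17 were lower (13 with edgeR, 21 with DESeq2), and 27 over the list alone (-1.61, 2.72e-27; adjusted p = 0.115 with an estimated correlation), such as Drc1 (26.2 ± 2.86 against 149 ± 13.1 CPM, -2.49 ± 0.41, FDR 0.00211), Tcte1 (-2.75 ± 0.44, FDR 0.00183) and Hydin (-2.86 ± 0.51, FDR 0.00347). Assembly factors had 7 of 12 lower (1 with edgeR, 9 with DESeq2), and 12 over the list alone (-1.30, 1.61e-11; adjusted p = 0.115 with an estimated correlation), with Lrrc6 at 17.7 ± 0.49 against 65.9 ± 13.01 CPM (-1.85 ± 0.42, FDR 0.0182); of the 7, Dnaaf3 lost its call with replicate as a block (0.0553). Intraflagellar transport genes had 9 of 27 lower (6 with edgeR, 14 with DESeq2), and 20 over the list alone (-0.80, 1.40e-17; adjusted p = 0.115 with an estimated correlation), with Traf3ip1 at 44.4 ± 12.2 against 193 ± 10.8 CPM (-2.13 ± 0.27, FDR 0.000263) and Ift172 at -1.05 ± 0.19 (FDR 0.00456). The BBSome had 2 of 9 lower (1 with edgeR, 3 with DESeq2), and 5 over the list alone (-0.60, 2.86e-05; adjusted p = 0.115 with an estimated correlation): Bbs9 (-0.82 ± 0.19, FDR 0.0215) and Bbs1 (-1.01 ± 0.25, FDR 0.0278). None of these lists lost its call with a library left out.

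Secretory markers had 2 of 15 lower at day 14, and 6 over the list alone (median -0.84, camera adjusted p 0.00114; adjusted p = 0.191 with an estimated correlation): Bpifb1 (2.75 ± 1.04 against 46.4 ± 11.05 CPM, -3.86 ± 0.35, FDR 2.60e-05) and Muc5b (-1.29 ± 0.29, FDR 0.0142). Squamous markers had 3 of 16 higher, and 4 over the list alone (0.89, 8.73e-07; adjusted p = 0.115 with an estimated correlation), with Krt4 at 930.2 ± 90.2 against 358 ± 55.4 CPM (1.38 ± 0.27, FDR 0.007). Basal markers had 1 of 17 higher, Pdpn (list 0.000578; adjusted p = 0.115 with an estimated correlation). Of 15 Notch pathway genes 2 were lower (camera adjusted p 0.259): Hes6 (106 ± 10.3 against 216 ± 44.4 CPM, -1.002 ± 0.166, FDR 0.00211) and Lfng (-0.95 ± 0.20, FDR 0.0102). Inflammation genes had 0 of 17 called by limma and edgeR, 1 by DESeq2 and 3 at an unadjusted p under 0.05 (median 0.99, 2.57e-05; adjusted p = 0.254 with an estimated correlation). Fibroblast markers had 0 of 11 at all 3 tools and at an unadjusted p under 0.05 (median 0.87, 0.00701; adjusted p = 0.429 with an estimated correlation), and neuroendocrine markers 0 of 8 called by any tool and 2 at that p (0.70, 0.00264; adjusted p = 0.368 with an estimated correlation). The fibroblast call was lost without labelled knockout day 14 replicate 1, where the median turned to -0.25 (0.859). The inflammation (0.60, 0.0521) and neuroendocrine (0.32, 0.415) calls were lost without labelled knockout day 14 replicate 2. The secretory median was -0.40 without that library.

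In all, 653 genes were called at day 14, 64 higher and 589 lower. The count was 335 without wild type day 14 replicate 2, 314 without wild type day 14 replicate 3, 253 without labelled knockout day 14 replicate 1 and 262 without labelled knockout day 14 replicate 2. Of 48 called genes named by the rule 23 kept their call with each library left out, among them Sntn, Cdhr4, Krt13, Tgm3, Cybb, Dnahc6, Dnahc3, Dnahc10, Tcte1, Drc1, Traf3ip1, Bpifb1 and Hes6. Rfx2 (FDR 0.145), Ift172 (0.0975) and Lfng (0.178) were among those that lost their call without labelled knockout day 14 replicate 2, and without replicate 1 so did Hydin (0.0624), Krt4 (0.0850) and Muc5b (0.177). Without labelled knockout day 14 replicate 2 the FDR also reached 0.129 for Lrrc6, 0.132 for Ccdc78, 0.335 for Bbs9, 0.307 for Bbs1 and 0.214 for Pdpn, and these 5 and Lfng also lost the call without wild type day 14 replicate 2.

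How did the cultures labelled knockout themselves change with time? Like wild type they gained regulators of multiciliated cells and axonemal genes while most squamous and basal genes on the lists fell. Most proliferation genes on their list were called lower as well, while fewer were in wild type. These call counts do not test a difference between genotypes. For the difference in change to day 14, edgeR called 0 of the 25 and DESeq2 called 1. The list median of that difference was -1.63, and -0.79 without labelled knockout day 0 replicate 1. Dnahc6 rose from 0.15 ± 0.02 CPM at day 0 to 31.6 ± 3.34 CPM at day 14 (5.63 ± 0.42, FDR 1.17e-07), and Dnahc5 from 0.63 ± 0.16 to 112 ± 26.0 CPM (6.62 ± 0.45, FDR 4.24e-08). Ccno rose by 6.20 ± 0.34 (FDR 6.39e-09), Gmnc by 6.16 ± 0.36 (FDR 7.90e-09) and Foxj1 from 21.7 ± 0.83 to 271 ± 88.5 CPM (3.57 ± 0.34, FDR 1.07e-06). Rfx2 was not called (0.56 ± 0.29, FDR 0.162). Trp73 fell by 1.10 ± 0.39 (FDR 0.0426), a call lost without labelled knockout day 14 replicate 2 or either labelled-knockout library of day 0 (highest FDR 0.334, without the former). Ndufa4l2 fell by 8.68 ± 0.37 (FDR 3.24e-10) and Krt5, a keratin of basal cells, changed by -2.41 ± 0.35 (FDR 5.82e-05).

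By day 14 in the labelled knockout 23 of 24 dynein arm genes rose (median 4.27, camera adjusted p 9.13e-22), with 27 of 28 radial spoke genes (3.67, 9.25e-22), all 12 assembly factors (2.60, 9.59e-10) and all 17 centriole amplification genes (1.48, 1.13e-10). So did 20 of 27 intraflagellar transport genes (1.18, 7.78e-12), 8 of 9 BBSome genes (1.22, 5.45e-06) and 8 of 12 regulators (4.13, 1.22e-08). Basal markers had 11 of 17 down and 2 up (-1.61, 0.00017), squamous markers 12 of 16 down (-2.80, 6.87e-06) and immediate early and heat shock genes 10 of 14 down (-1.66, 2.62e-05). All 10 of these lists had adjusted p = 0.0965 with an estimated correlation. Of 25 proliferation genes 20 fell (-2.09, camera adjusted p 8.74e-07; adjusted p = 0.306 with an estimated correlation), among them Mki67 (117 ± 99.5 to 8.15 ± 1.44 CPM, -3.46 ± 0.67, FDR 0.000768). Of 17 inflammation genes 9 fell and 1 rose (-1.98, 0.000218; adjusted p = 0.251 with an estimated correlation), with Cxcl2 at -5.14 ± 0.43 (FDR 3.20e-07). Secretory markers had 5 of 15 up and 1 down (0.78, 0.00832; adjusted p = 0.231 with an estimated correlation), and the call was lost without labelled knockout day 0 replicate 1 (median 0.16, 0.0623). The proliferation median was -1.29 without that library. Ionocyte markers had 4 of 9 up and 1 down (1.06, 0.0152; adjusted p = 0.231 with an estimated correlation), with Foxi1 at 2.26 ± 0.41 (FDR 0.000427), and smooth muscle markers 4 of 6 down (-2.24, 0.0138; adjusted p = 0.128 with an estimated correlation). The ionocyte call was lost without labelled knockout day 14 replicate 2 (0.0749) and the smooth muscle call without replicate 1 (0.0549).

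In the labelled knockout 3158 genes were called at day 4 against day 0 (1447 higher, 1711 lower), 4203 at day 7 (1967 higher, 2236 lower) and 5052 at day 14 (2276 higher, 2776 lower). Without labelled knockout day 4 replicate 1 or 2 the day 4 count was 2055 or 1960, and without labelled knockout day 7 replicate 2 the day 7 count was 2780. With the libraries compared alone the counts were 1594, 2467 and 3260. By library size alone the higher share of calls was 56.2%, 62.3% and 58.1% against 45.8%, 46.8% and 45.1%, so the balance of higher and lower genes rests on the scaling. Of 105 called genes named by the rule at day 14, 91 kept their call with each library left out. Wild type and labelled knockout shared 1984 genes that rose by day 14, against 495 for independent lists. Here too the same variance estimate for each gene serves both lists, so some excess was built in.

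Did the change itself differ between genotypes? From day 0 to day 14 it differed for 157 genes, 154 of them with a lower change (knockout minus wild type) in the labelled knockout. The difference was -2.38 ± 0.55 for Dnahc6 (FDR 0.048), while Muc5b (1.76 ± 0.40, FDR 0.048) and Muc5ac (1.62 ± 0.37, FDR 0.048) went the other way. For Trp73 it was -4.56 ± 0.51 (FDR 0.000761), and for Cxcl2 -3.20 ± 0.55 (FDR 0.01). Rfx2 (-1.41 ± 0.38, FDR 0.0998) and Foxj1 (-1.13 ± 0.44, FDR 0.345) did not pass. With replicate as a block within each genotype Rfx2 did (-1.41, FDR 0.0315), as did Hes6 (-0.999, FDR 0.0424), the assembly factor Heatr2 (-0.77, FDR 0.0434) and the p53 target Perp (-0.73, FDR 0.0422). The count of 157 then became 392. Day 0 replicate numbers mostly failed the pairing check against later days, so that block was not the main fit. The change to day 4 differed for 3 genes and the change to day 7 for 24.

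By list, 4 of 24 dynein arm genes passed for the change to day 14, and 16 over the list alone (median -1.63, camera adjusted p 1.75e-15; adjusted p = 0.376 with an estimated correlation), while edgeR and DESeq2 called 0. The 4 were Dnahc6, Dnahc3 (-2.95 ± 0.67, FDR 0.0469), Dnahc10 (-2.27 ± 0.49, FDR 0.0385) and Dnahc7a (FDR 0.0457). Radial spoke genes had 1 of 28, Ccdc135 (-2.53 ± 0.57, FDR 0.0463), and 11 over the list alone (-1.27, 1.93e-13; adjusted p = 0.376 with an estimated correlation), while edgeR called 0 and DESeq2 1. Intraflagellar transport had 1 of 27, Traf3ip1 (-1.69 ± 0.38, FDR 0.0457; list -0.57, 9.38e-07; adjusted p = 0.400 with an estimated correlation), while edgeR called 0 and DESeq2 1. Assembly factors had 0 of 12 with the 3 tools in their unblocked fits, 8 at an unadjusted p under 0.05 and 6 over the list alone (-1.22, 8.02e-08; adjusted p = 0.376 with an estimated correlation). Proliferation had 0 of 25 with limma and edgeR, 1 with DESeq2 and 11 at an unadjusted p under 0.05 (-1.63, 2.88e-08; adjusted p = 0.400 with an estimated correlation). The secretory (0.67, 0.000313; adjusted p = 0.376 with an estimated correlation), goblet (0.99, 0.00336; adjusted p = 0.400 with an estimated correlation) and neuroendocrine lists (1.26, 5.84e-05; adjusted p = 0.376 with an estimated correlation) shifted up. The inflammation (-1.24, 0.0032; adjusted p = 0.459 with an estimated correlation) and squamous lists (-0.87, 0.00349; adjusted p = 0.400 with an estimated correlation) shifted down. The regulators were not called as a list (-0.19, 0.958), and DESeq2 called 1 of the 12 with a positive difference. The neuroendocrine median ranged from 0.77 without wild type day 0 replicate 2 to 1.93 without labelled knockout day 0 replicate 2. Without labelled knockout day 0 replicate 1 the proliferation (median -0.79, 0.0557) and secretory (0.23, 0.0858) calls were lost. The squamous call was lost without replicate 2 (-0.51, 0.504). Without labelled knockout day 14 replicate 1 the squamous (0.0699) and inflammation (0.188) calls were lost, and the goblet call without labelled knockout day 14 replicate 2 (median 0.57, 0.112) or wild type day 0 replicate 1 (0.59, 0.0750).

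The count of 157 was 93 without wild type day 0 replicate 2, 63 without wild type day 0 replicate 3, 91 without labelled knockout day 0 replicate 2, 63 without wild type day 14 replicate 2, 64 without wild type day 14 replicate 3, 35 without labelled knockout day 14 replicate 1 and 64 without labelled knockout day 14 replicate 2. edgeR on recovered reads gave 18, and of the 10 genes named above with a call only Trp73 kept it with each library left out. Cxcl2 lost it without labelled knockout day 14 replicate 1 (FDR 0.0737). The other 8 lost it without 8 or more of the 10 libraries, with the highest FDR without labelled knockout day 14 replicate 1 for Dnahc7a (0.190) and Muc5ac (0.170), and without replicate 2 for Dnahc10 (0.163), Dnahc3 (0.196), Dnahc6 (0.194), Ccdc135 (0.200), Traf3ip1 (0.223) and Muc5b (0.230). The day 4 count of 3 was 0 without wild type day 0 replicate 3 or wild type day 4 replicate 2, 1 without wild type day 4 replicate 3 or labelled knockout day 4 replicate 2, 13 and 8 without labelled knockout day 0 replicates 1 and 2, and 21 without wild type day 4 replicate 1. The day 7 count of 24 was 9 and 8 without wild type day 0 replicates 1 and 3, 47 without labelled knockout day 0 replicate 1, 12 and 5 without wild type day 7 replicates 1 and 3, and 1 and 6 without labelled knockout day 7 replicates 1 and 2. edgeR gave 1 at day 4 and 7 at day 7, and DESeq2 18 and 46.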

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

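The results marked here are those whose change from day 0 differed between genotypes with an FDR under 0.05. They were 3 genes at day 4, 24 at day 7 and 157 at day 14. At day 4 they were Trp73 (-3.54), Grik3 (-3.90) and Prss12 (-2.75), the last of which were named only because they passed, after the values were seen. At day 14, 28 of the named genes were marked. The largest were Dmkn (-7.93), Sntn (-5.36), Sprr2g (-5.19), Cdhr4 (-4.90) and Cdhr1 (-4.86). Ldlrad1 stood at -4.58, Trp73 at -4.56, Abp1 at -4.51, Slc16a3 at -4.26, Fam216b at -4.23 and Fam166b at -4.12. Pglyrp4 (-4.09), Stoml3 (-4.02), Diras2 (-3.81), Ttc29 (-3.65) and Jam3 (-3.56) came next. Unc79 stood at -3.41, Plxnb3 at -3.40, Cxcl2 at -3.20, Dnahc3 at -2.95, Ccdc135 at -2.53 and Dnahc6 at -2.38. The smallest were Dnahc10 (-2.27), Dnahc7a (-2.26) and Traf3ip1 (-1.69), and Muc5b (1.76), Muc5ac (1.62) and Cadm2 (1.88) had the opposite sign. Of the 28, 10 were rerun for this comparison with each library left out, and 9 of those lost the call in at least 1 run. The rest were not rerun for it. A negative value can come from a higher level at day 0, as for Trp73, and need not mean a lower level at day 14.

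The first pattern was the lower axonemal genes in libraries labelled knockout at day 14; of its 4 tests, the bounds for fewer multiciliated cells and for a delay being made up were written after the result was seen, and those for an earlier point of the wild-type course and for transcript length before, while the run without the libraries titled day 3, the pairs and the levels of genes of similar length were added after. Fewer multiciliated cells, with their stages in unchanged proportion, would lower regulators and axonemal genes alike. The mean of 8 regulators minus that of 58 axonemal genes was instead higher in labelled knockout by 1.73 ± 0.27 (SE, n = 2 against n = 3). That argues only against such an even loss as the only cause. In wild type the same difference was higher in every library at day 4 than in any library at day 14. It therefore shifts with stage, and the test cannot decide on fewer mature cells with earlier stages kept. An earlier point of the wild-type course stays open: 1.59% of 63 axonemal genes lay outside the range from wild type day 4 to day 7 with a median 0.01 above wild type day 4, but the match rests on wild type day 4 replicate 1, titled day 3 (mean log2 3.27 against 4.75 and 4.75), and without both libraries titled day 3 34.9% lay outside, all below wild type day 4 (median -0.45). A delay being made up stays open too: from day 7 to day 14 the axonemal mean changed by -0.0945 (SE 0.186, or 0.190 from pairs; 0.10 and -0.28 by replicate), and the gap of 0.393 to 25% of the wild-type rise from day 4 to day 7 was within 2 SE, 0.451 unpaired and 0.437 paired, when the error of that rise was counted, as a first version of the bound had not done. Transcript length could not account for the pattern, as it needs genes of similar length to be lower by as much, while these 11776 genes had a median of -0.01 (quartiles -0.22 and 0.17), 4 equal groups by transcript length had medians of 0.001, -0.019, -0.020 and 0.003, and the axonemal median was -1.60, or -1.61 relative to genes of similar length.

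The next pattern was higher squamous and lower secretory markers at day 0; the test of a single library was set before the result was seen, and the test of cell share after. A single library could not account for it, since both lists kept their call with each day 0 library left out (highest adjusted p 2.76e-06). Over these runs the squamous median ranged from 1.295 to 2.793 and the secretory median from -1.466 to -0.972. The exclusion covers the direction of both medians only. The adjusted p used the preset correlation, the runs were not repeated with an estimated one, and some left a lone labelled-knockout library. A lower share of secretory cells would raise basal and squamous markers alike, but the squamous median exceeded the basal median by 1.63. That argues only against a fall in secretory cells with other cell types in unchanged proportion as the only cause. The permutation p of 0.00116 came from shuffling genes between these lists. It treats genes as independent and does not measure the spread between libraries. Other causes of the day 0 difference, such as the state of the cultures before the air interface, were not tested.

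The last pattern was called genes near Trp73 on chromosome 4, and both of its tests were written after the result was seen. A segment linked to the targeted gene may carry differences of strain: 16 of 149 tested genes within 10 Mb were called at 1 or more days against 1026 of 15429 elsewhere, an odds ratio of 1.69 (95% interval 0.93 to 2.86, Fisher exact p 0.0666), which does not decide it. That count takes a call at any day, and most of the 16 were called at 1 or 2 days. Gm13157 (2.73, 2.89, 2.67 and 2.47) and Znf41-ps (1.41, 1.06, 1.46 and 1.53) were called higher at days 0, 4, 7 and 14. Both carry predicted or pseudogene names and drop out of the next test. Without predicted and clone-named genes the odds ratio was 1.45 (0.70 to 2.72, Fisher exact p 0.260). The bound first written for that second test, an odds ratio under 1.5, was met; a condition on the excess itself was then added, under which the test cannot tell.

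For the wild-type comparisons over time, regrouping the 6 libraries gives 10 splits, so a share under 0.05 cannot be reached. The real grouping alone, 1 of 10 splits, gave its count at days 4, 7 and 14 (4250, 5599 and 6359 genes), and the highest other split gave 5, 0 and 0 genes. Each other split mixes day 0 with later libraries, so the day difference adds to the spread within its groups. Low counts there were built in, and the splits do not decide on chance.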

How the results depend on the processing

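Limits are the small groups (2 or 3 libraries), counts that moved when 1 library of either genotype was left out or when only the libraries compared were fitted, and a share of higher genes over time that depended on the scaling. Of 81 list calls 78 were lost with a correlation estimated from the data, and fry lost 36. The cause was not tested for any of these shifts.

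With each library left out in turn, the number of genes called between genotypes ranged from 194 to 489 at day 0 (350 with all libraries), 44 to 311 at day 4 (180), 36 to 167 at day 7 (246) and 253 to 650.0 at day 14 (653). Over time it ranged from 2929 to 4828, 4338 to 5984 and 5257 to 6702 in wild type at days 4, 7 and 14, and from 1960.0 to 2656, 2780.0 to 3632 and 3471 to 4523 in labelled knockout. For a different change from day 0 it ranged from 0 to 21 at day 4 (limma; 454 at an unadjusted p under 0.05 with all libraries), 1 to 47 at day 7 and 35 to 173 at day 14. The goblet list at day 4, not called with all libraries, had a median of 0.52 without labelled knockout replicate 1 and turned to -0.497 without replicate 2 (adjusted p 0.0229).

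Counts also moved with the filter and the model. For a different change, the day 4 count without a low-count filter was 14, and with 1 CPM in 5 libraries the 3 counts were 1, 13 and 89. DESeq2 on recovered reads gave 18 at day 4 and 46 at day 7, and only the libraries compared gave 0 at day 4 (limma; 286 at an unadjusted p under 0.05). DESeq2 called 577, 362 and 524 genes between genotypes at days 0, 4 and 7. With only the libraries compared, the counts were 2, 50 and 402 between genotypes at those days and 1594, 2467 and 3260 in labelled knockout over time. With replicate as a block, day 4 between genotypes gave 291, and the counts for a different change were 9, 55 and 392; the time comparisons, all against day 0, were treated as unpaired. By library size alone, median changes shifted by more than 0.1 in wild type at day 7 (0.12) and in labelled knockout at days 7 (0.16) and 14 (0.14).

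Alternatives chosen after seeing the data, among them the edgeR test first planned as main, also moved these counts. For a different change, edgeR on recovered reads gave 1, 7 and 18, a pseudocount of 0.1 CPM gave 1, 8 and 64, and a pseudocount of 2 CPM gave 17, 41 and 264. Without both day 4 libraries titled day 3, day 4 gave 285 between genotypes and 10 for a different change.

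Of all results for the named genes, called or not, DESeq2 left 578 as they were, made 8 weaker and 8 stronger, edgeR weakened 31, no filter 29, only the libraries compared 58, a pseudocount of 0.1 CPM 23 and leave-one-out 355 of all its comparisons, with no reversal. For lists, leave-one-out left 411 as they were, weakened 42, strengthened 48 and reversed 1, relative log expression weakened 2, and the replicate block weakened 6 and strengthened 5.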

Other observations

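A set of 29 genes was called between genotypes at all 4 days, 25 higher and 4 lower in the libraries labelled knockout each day. Gm13157 and Znf41-ps, both within 10 Mb of Trp73, were among the higher genes. The higher genes included regulators of epithelial barrier fate: Grhl3 (1.86, 2.88, 2.60 and 1.501 at days 0, 4, 7 and 14; FDR 0.0154, 0.000881, 0.00278 and 0.0361; SE 0.39 each day) and Prdm1 (1.68, 2.55, 1.78 and 1.53; SE 0.37). The membrane mucin Muc13 (1.72, 2.27, 2.64 and 2.26; SE 0.40), the pantetheinase Vnn1 (2.59, 3.77, 4.16 and 2.26; SE 0.58) and the sterol hydroxylase Cyp27a1 (2.77, 3.65, 3.21 and 2.42; SE 0.45) were also higher each day, beside Tgm3, Krt13, Krt4 and Krt6b. The lower genes were Muc5b, Bpifb1, Apbb1 (-0.98, -0.84, -0.95 and -1.502; SE 0.17) and Atp6v1c2, a subunit of the vacuolar proton pump on the ionocyte list (-1.16, -1.09, -1.29 and -1.66; SE 0.21). Grhl3, Prdm1, Muc13, Cyp27a1, Apbb1, Gm13157 and Znf41-ps were outside the rule for named genes and were not rerun with a library left out. Atp6v1c2 lost its call without labelled knockout replicate 1 at days 4 (-0.87) and 7 (-1.12). At day 4 Atp6v1c2 also lost it without wild type replicate 3 (-1.05, FDR 0.0566). Vnn1 lost its call at day 7 without labelled knockout replicate 2. Krt6b lost its day 14 call without any 1 of the 5 libraries (highest FDR 0.399, without labelled knockout replicate 2), and Krt4 its day 7 call without either labelled-knockout library or wild type replicate 3 (highest FDR 0.0990).

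Of 20 targets of p53, 9 fell and 3 rose in wild type by day 14 (camera adjusted p 0.0739), with the apoptosis gene Pmaip1 at -2.94 ± 0.32 (FDR 1.64e-06), and 7 fell in labelled knockout (0.0627). Between genotypes at day 0, limma and edgeR called 0 of the 20, DESeq2 called 1 and 2 passed an unadjusted p under 0.05 (camera adjusted p 0.104). Perp, an epithelial target of p53 family members, stood at 0.99 ± 0.26 at day 0 (FDR 0.0634). With replicate as a block it was higher at days 0, 4 and 7 (1.01, 0.90 and 0.59; FDR 0.000216, 0.00103 and 0.0201), and the p53 list was called at day 0 (median 0.15, adjusted p 0.0380) and day 7 (0.05, 0.0236). Tuft markers had 4 of 9 up and 1 down in wild type by day 14 (0.580), ionocyte markers 5 of 9 up and 1 down (0.119), neuroendocrine markers 1 of 8 up (0.694), Notch genes 2 of 15 up and 3 down, and interferon genes 2 of 20 up and 3 down (0.948).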
